A study of Homo sapiens with 6 samples.

How the data were processed

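RNA sequencing was done on KGN cells, 3 libraries without drug and 3 libraries with 10 µM cisplatin, all at 48 h. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with an mRNA kit. Per the submitters' processing notes, Bowtie2 2.4.5, RSEM 1.3.1 and the mouse build mm10 were used, with no role given. The deposited FPKM table, however, holds 33774 human Ensembl gene identifiers with one column per library, and its positions match GRCh38: 99.5% of the genes are in GENCODE 29, and 95.8% have the same position there. Coordinates printed are those of the deposited table, counted from 1 on GRCh38. The aligner settings, the counting and the use of strand are not given in the sources used here.

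FPKM, as deposited by the authors, is reads per kilobase of merged exons, scaled to the reads assigned in a library. The values proved to be whole reads times one step per library. With the merged exon lengths of GENCODE 29, all 6 values were whole reads within a tolerance of 0.0001 for 94.2% of genes, and for the other 1944 genes the length was solved from the values themselves. The totals behind the scaling came to 19360417, 19467238 and 19499315 reads in control replicates 1 to 3 and to 19169585, 17476168 and 18953465 in cisplatin replicates 1 to 3. Recovered reads summed to 1.02 times these totals. Depth was thus similar between the groups. In FPKM, a rise of abundant genes lowers all others, and the values were not scaled between libraries.

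The main analysis used the values as deposited. Genes with an FPKM of at least 1 in at least 3 of 6 libraries were kept (13208 genes), and log2(FPKM + 1), a pseudocount of 1, was fitted with limma 3.58.1 (lmFit, eBayes with trend and robust, two-sided) in R 4.3.3 with statmod 1.5.0, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every log2 fold change is cisplatin minus control on this scale, which compresses the change of genes with low values. No block was fitted, since the labels do not say that replicate numbers mark a shared culture or day. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the preparation and the figures.

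There were 29 gene lists with 770 entries, fixed before the data were examined together with the tests and the rule for named genes, and matched on current or older symbols. They were p53 targets, G2/M and mitosis, G1/S and DNA replication, replication-dependent histones, homologous recombination and crosslink repair, nucleotide excision repair, damage checkpoint, apoptosis regulators, steroidogenic genes, cholesterol synthesis and uptake, granulosa markers, secreted inflammatory genes, interferon-stimulated genes, NRF2 and glutathione, ATF4 and unfolded protein response, immediate early genes, TGF-beta and matrix, platinum transport and metallothioneins, autophagy and lysosome, mitochondrial mRNAs, nuclear oxidative phosphorylation, glycolysis, ribosomal proteins, nuclear retained transcripts, and markers of fibroblasts, epithelium, immune cells, endothelium, and theca cells and oocytes. Each list was tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation, adjusted over the lists. No list passed with the estimated correlation. Members were counted with p adjusted over all genes and over the list alone.

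Named genes were the 8 largest rises and the 8 largest falls in log2 fold change among genes past the threshold, with a mean of at least 5 FPKM in the higher group and no overlap between the libraries of the groups; a fixed panel, of which CDKN1A, MDM2, FOXL2, CYP19A1 and STAR are described; and for each list up to 3 members past the threshold with the largest absolute change, or, if none passed, up to 2 with the highest mean FPKM. Other genes named beside these were chosen after their values were seen. Of 92 named genes, 46 are overlapped by another gene of the table, 39 of them on the other strand, and only some of these overlaps are mentioned below. Partners with a higher mean FPKM than the named gene in both groups include LIPA for IFIT2, TCP1 for ACAT2, STT3A for CHEK1 and RPL7P1 for CSF1R. Gene span was the distance from start to end in the deposited table, and sets of genes over 100 kb and under 10 kb were tested with camera. Values per library were compared between groups with exact permutation tests, which cannot go below 0.1 for 3 against 3.

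The fit was tested on simulated reads for the comparison of cisplatin with control, with 12448 genes tested and 200 genes changed. It recovered 51.0% of genes changed 1.2-fold, 92.0% of those changed 1.5-fold, 94.0% of those changed 2-fold and 100% of those changed 4-fold, with 14 false calls of 180. Genes changed 4-fold had a median log2 fold change of 1.66. The simulation raised and lowered genes alike, with the same spread for every gene and no length or GC bias of a library. In the real data 72.4% of the genes tested were called. The recovery and the false calls therefore do not carry over to so broad a change, to its dependence on scaling or to a biased library.

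Alternatives tried were pseudocounts of 0.1 and 0.5, no filter and a filter of 5 FPKM, TPM, TPM without the highest and mitochondrial genes, trimmed mean of M values, median of ratios and quantile scaling, the replicate number as a block, no trend, library weights, each library left out in turn, fry in place of camera, other span limits and matching on expression. The recovered reads with limma's voom (13208 genes, 4727 rose and 4654 fell) and a test of protein-coding genes only were chosen after the data were seen. All per-sample columns were used.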

Results

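Messenger RNA of KGN cells, an established human ovarian granulosa-like tumour line, was sequenced after 48 h with 10 µM cisplatin or after 48 h of culture without the drug. Cisplatin is a platinum compound that forms crosslinks in DNA, and the comparison asks which transcripts differed after this exposure. There were 3 libraries per group, and the table gave FPKM for 33774 genes in each of the 6 libraries. Reads behind the scaling of a library, recovered from the values, ranged from 17476168 in cisplatin replicate 2 to 19499315 in control replicate 3. The labels do not say whether replicates of a group came from separate cultures. The p-value of a gene or of a value per library thus measures only the spread between these samples, which may be technical. Camera and the permutations over mitochondrial genes also compare genes with each other, and reach no further than these samples.

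GDF15 and CDKN1A were among the genes that rose in cisplatin-treated cells, and genes of cell division among those that fell. GDF15, a secreted stress cytokine, rose from 48.2 ± 4.98 FPKM in control cells to 1458 ± 164 (SD, n = 3 per group). ANLN, an actin-binding protein needed for cytokinesis, fell from 98.1 ± 2.51 to 2.08 ± 0.192 FPKM (SD, n = 3). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose from 218 ± 23.1 to 2035 ± 104 FPKM (SD, n = 3), and MDM2, an E3 ubiquitin ligase, from 7.67 ± 0.373 to 42.0 ± 3.10 FPKM. Of 13208 genes tested, 6067 rose and 3499 fell, and 1092 rose and 943 fell by at least 2-fold on the scale of log2(FPKM + 1), which understates the change of genes with low values. The median log2 fold change of all genes was 0.17, and the share of the called genes that rose, 63.4% with the deposited values, was 49.6% (4599 rose, 4670 fell) with trimmed mean of M values scaling, 49.8% with median of ratios scaling, 54.1% with quantile normalization, 59.8% with TPM scaling and 54.5% with TPM scaling without the highest and mitochondrial genes. Changes of at least 2-fold leaned to falls with trimmed mean of M values (731 rose, 1212 fell), median of ratios (733 and 1205) and quantile scaling (840 and 1076). They did so too with TPM scaling without the highest and mitochondrial genes (1298 and 1483), but not with TPM scaling (1450 and 1319). No gene called with the deposited values was called in the opposite direction under any of these scalings, but calls were lost. Of 9566 genes called with the deposited values, 8098 kept the call with trimmed mean of M values and 8113 with median of ratios. The numbers were 8592 with quantile normalization, 9052 with TPM scaling and 8494 with TPM scaling without the highest and mitochondrial genes. Such scalings shift genes largely together, so opposite calls were unlikely.

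Among the 8 largest rises, GDF15 (chromosome 19, 18374731 to 18389176) had a log2 fold change of 4.89 (SE 0.11, adjusted p = 7.66e-08). AREG, a ligand of the epidermal growth factor receptor (chromosome 4, 74445134 to 74455009), rose by 4.77 (SE 0.12), and BEX2 (chromosome X, 103309346 to 103311046) by 4.77 (SE 0.12). LCE1F, a late cornified envelope gene (chromosome 1, 152776372 to 152776728), had no read in any control library and 19.6 ± 4.08 FPKM after cisplatin (SD, n = 3), at least 45.3-fold higher than a floor of 3 reads per control library. AL158206.1, a gene of the sense overlapping class on chromosome 9, rose from 1.22 to 29.3 FPKM. PSTPIP2 rose from 1.33 to 27.8 FPKM. SAT1, the rate-limiting enzyme of polyamine catabolism, rose from 44.0 to 511 FPKM, and MAFF, a small basic leucine zipper transcription factor, from 1.89 to 31.0 FPKM. All 8 had an adjusted p of 2.42e-07 or less. That the libraries of the groups do not overlap was a condition of their choice.

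The 8 largest falls were led by ANLN (chromosome 7, 36389806 to 36453791), with a log2 fold change of -5.01 (SE 0.06, adjusted p = 4.72e-08). Genes of mitosis made up most of this set. CDC20, an activator of the anaphase-promoting complex, fell from 46.7 to 0.888 FPKM, TOP2A, a DNA topoisomerase, from 53.5 to 1.36, UBE2C from 47.0 to 1.60, CCNB1, which encodes cyclin B1, from 76.5 to 3.38, and CEP55, a midbody protein, from 45.4 to 1.65. COL3A1, a fibrillar collagen gene, fell from 63.8 to 2.06 FPKM. AC099850.3, annotated as antisense on chromosome 17, fell from 44.1 to 1.01 FPKM, but it overlaps PRR11 on the other strand, which fell as well (13.9 to 0.294), and without strand in the counting their reads cannot be told apart.

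**Figure D1:**
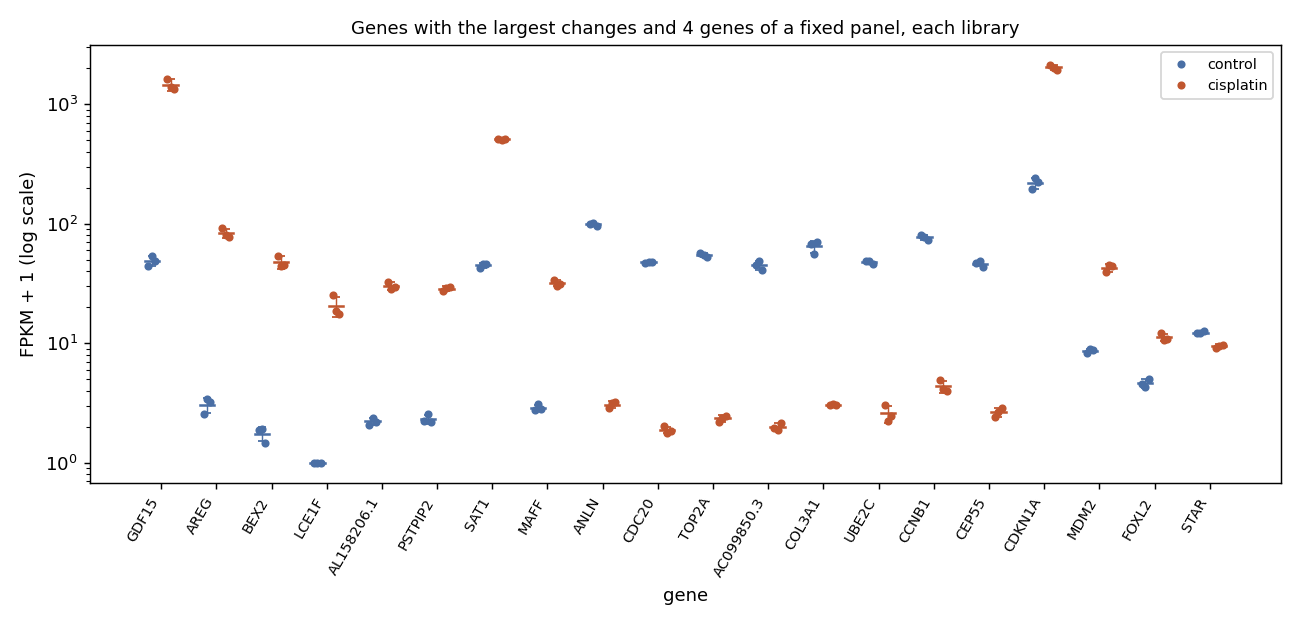
FPKM + 1 on a log axis for the 8 genes with the largest rise, the 8 with the largest fall and 4 genes of a fixed panel, where points are libraries, horizontal lines are group means and bars are SD (n = 3 per group). The control and cisplatin libraries do not overlap for any gene shown. This was a condition for the largest rises and falls, but not for the panel. STAR has the smallest distance between the group means (11.3 and 8.47 FPKM), and LCE1F is at 0 FPKM in each control library.

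The fixed panel also held genes of ovarian function. FOXL2, a transcription factor of granulosa cells, rose from 3.66 ± 0.388 to 10.2 ± 0.794 FPKM. STAR, which moves cholesterol into mitochondria for steroid synthesis, fell from 11.3 ± 0.298 to 8.47 ± 0.327 FPKM, but it overlaps ASH2L on the other strand, which was at 12.3 and 7.78 FPKM. CYP19A1, which encodes aromatase, had 0 to 8 reads in control and 1 or 2 reads in cisplatin libraries and was not tested.

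p53 target genes rose as a group. All 36 members rose, adjusted over all genes and also adjusted over the list alone, and their median log2 change lay 2.07 above that of all genes. After GDF15 and CDKN1A, the largest change among them was that of FDXR, a mitochondrial ferredoxin reductase, which rose from 5.60 to 55.0 FPKM. With camera the list had an adjusted p of 2.67e-12 at the preset correlation and an adjusted p = 0.0855 with an estimated correlation. Of 29 apoptosis regulators tested, 20 rose, 3 fell and 6 did not pass, with the same counts adjusted over the list alone. TNFRSF10B, a death receptor for TRAIL, rose from 27.8 to 161 FPKM, and FAS, which overlaps ACTA2 on the other strand, from 12.1 to 50.2 FPKM. BID, CASP2 and CASP6 fell. Camera gave these regulators an adjusted p of 0.00394 and an adjusted p = 0.171 with an estimated correlation, and it shares 4 genes with the p53 targets.

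Nearly all cell cycle genes tested fell. All 36 genes of G2/M and mitosis fell, adjusted over all genes and adjusted over the list alone, with a median 3.80 below that of all genes (camera adjusted p = 2.23e-26). The adjusted p = 0.0855 with an estimated correlation. Of the 35 genes of G1/S and DNA replication, 33 fell and 2 rose, again also adjusted over the list alone. RRM2, a subunit of ribonucleotide reductase, fell from 37.0 to 1.82 FPKM, TK1, thymidine kinase, from 44.5 to 4.38 FPKM, and MCM4, part of the replicative helicase, from 23.7 to 2.68 FPKM. The members that rose were CCND1, which encodes cyclin D1 (log2 fold change 1.54), and PCNA, the sliding clamp of replication (0.78). This list had a camera adjusted p of 7.15e-16 and an adjusted p = 0.0855 with an estimated correlation. Replication-dependent histone genes moved the other way. There were 12 of 19 with values high enough for testing, and all 12 rose, also adjusted over the list alone, among them HIST1H2BJ (2.13 to 30.1 FPKM), HIST1H4H (2.51 to 28.9 FPKM) and HIST1H2BD (8.99 to 70.4 FPKM). Histone genes are near-identical copies, so their values are uncertain where reads could be split between copies. The libraries were made with an mRNA kit, so the values cover only the histone transcripts that it captured. Which forms these are, and whether total histone mRNA rose, was not tested. The list had a camera adjusted p of 1.003e-04 and an adjusted p = 0.225 with an estimated correlation.

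Most genes of homologous recombination fell, and those of nucleotide excision repair went both ways. Of 30 genes of homologous recombination and interstrand crosslink repair, 25 fell, 2 rose and 3 did not pass, and 26 fell and 2 rose adjusted over the list alone. FANCI fell from 10.9 to 0.636 FPKM, RAD51AP1 from 13.7 to 1.12 FPKM and EXO1, a nuclease of end resection, from 10.5 to 0.716 FPKM. RAD51C and PALB2 rose by 0.37 and 0.30 on the log2 scale with the deposited values, but with trimmed mean of M values scaling 27 members fell and 0 rose. Camera gave it an adjusted p of 3.09e-11 and an adjusted p = 0.154 with an estimated correlation. Nucleotide excision repair genes had 12 that rose, 6 that fell and 8 that did not pass of 26 tested (the same adjusted over the list alone), and 9 that rose and 10 that fell with trimmed mean of M values scaling. XPC and DDB2, damage recognition factors that are also p53 targets, rose from 4.59 to 23.3 FPKM and from 3.14 to 9.40 FPKM, while RPA1, a single-strand binding protein, fell from 23.5 to 8.17 FPKM. For these genes the camera adjusted p was 0.831 (adjusted p = 0.861 with an estimated correlation), and its median lay 0.05 below that of all genes although the test and the mean pointed up. Among 22 DNA damage checkpoint genes, 3 rose, 12 fell and 7 did not pass, and the counts were the same adjusted over the list alone. CLSPN, claspin, fell from 7.05 to 0.226 FPKM, TIMELESS from 14.6 to 2.56 FPKM and the kinase gene CHEK1 from 6.31 to 1.39 FPKM. Its camera adjusted p was 0.00279, and adjusted p = 0.227 with an estimated correlation.

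Most genes of the ATF4 and immediate early lists rose. Of 29 genes of ATF4 and the unfolded protein response, 21 rose, 6 fell and 2 did not pass, with 7 that fell adjusted over the list alone. ATF3 rose from 1.88 to 26.5 FPKM, DDIT3, which encodes CHOP, from 9.80 to 99.9 FPKM, and PPP1R15A, a phosphatase subunit that acts on eIF2alpha, from 21.8 to 195 FPKM. The members that fell were chaperones and folding enzymes of the endoplasmic reticulum, PDIA4, HSP90B1, CALR, PDIA6, DNAJC3 and SDF2L1, with log2 fold changes from -1.66 to -0.48. DDIT3 overlaps MARS on the other strand. As a set they had a camera adjusted p of 0.0116 and an adjusted p = 0.355 with an estimated correlation. Of 25 immediate early and AP-1 genes, 18 rose, 4 fell and 3 did not pass, also adjusted over the list alone. MAFF and ATF3 led the list, DUSP6, a phosphatase of ERK, rose from 0.507 to 10.5 FPKM, and FOS fell by 1.10 on the log2 scale. Its camera adjusted p was 0.00328, and adjusted p = 0.133 with an estimated correlation. NRF2 and glutathione genes went both ways, with 10 that rose, 14 that fell and 6 that did not pass of 30 (the same adjusted over the list alone). GPX1, glutathione peroxidase 1, rose from 127 to 507 FPKM, AKR1B10 from 4.79 to 17.2 FPKM and OSGIN1 from 3.87 to 13.7 FPKM. The list had a camera adjusted p of 0.180 (adjusted p = 0.588 with an estimated correlation), and its mean, 0.07, had another sign than its median, -0.07. The test, which compares the list with other genes, pointed down, and the list median minus that of all genes was -0.24.

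Nearly all tested interferon-stimulated genes and most tested secreted inflammatory genes rose. Of 30 interferon-stimulated genes tested, 28 rose and 2 did not pass, also adjusted over the list alone. ISG15, a ubiquitin-like modifier, rose from 135 ± 8.62 to 583 ± 115 FPKM (SD, n = 3), RSAD2, viperin, which overlaps CMPK2 on the other strand, from 14.1 to 58.8 FPKM and IFIT2 from 8.35 to 32.4 FPKM. Their median log2 change lay 0.83 above that of all genes, with a camera adjusted p of 1.87e-06 and an adjusted p = 0.272 with an estimated correlation. Among 15 secreted inflammatory and senescence-associated genes that were tested, 12 rose, 2 fell and 1 did not pass. The counts were the same adjusted over the list alone, and the rest of the 30 genes listed were absent or too low for testing. IGFBP3 rose from 21.2 to 132 FPKM and CSF2, the cytokine GM-CSF, from 0.283 to 4.71 FPKM, while IGFBP5 fell from 24.6 to 2.93 FPKM. Camera gave this set an adjusted p of 0.0198 and an adjusted p = 0.171 with an estimated correlation, and it did not pass without cisplatin replicate 1 (adjusted p = 0.0746), with a filter of 5 FPKM (0.202) or with library quality weights (0.0537). Autophagy and lysosome genes rose in 26 of 31 cases, fell in 3 and did not pass in 2, also adjusted over the list alone. MAP1LC3B, the LC3B protein of autophagosomes, rose from 37.3 to 170 FPKM, DRAM1 from 6.37 to 25.8 FPKM and GABARAPL1 from 18.6 to 43.1 FPKM. Its camera adjusted p was 0.000444, and adjusted p = 0.20 with an estimated correlation.

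Most tested genes of the matrix, cholesterol and glycolysis lists fell. Of 33 TGF-beta and extracellular matrix genes, 24 fell, 6 rose and 3 did not pass, also adjusted over the list alone. COL1A1 fell from 583 ± 49.9 to 39.4 ± 2.35 FPKM (SD, n = 3) and COL1A2, the other chain of type I collagen, from 289 ± 21.4 to 33.2 ± 0.881 FPKM. The camera adjusted p was 2.46e-07, and adjusted p = 0.133 with an estimated correlation. Among 24 genes of cholesterol synthesis and uptake, 19 fell, 3 rose and 2 did not pass, with the same counts adjusted over the list alone. ACAT2 fell from 16.3 to 2.87 FPKM, INSIG1, a sterol sensor protein, from 72.2 to 21.4 FPKM, and HMGCS1, HMG-CoA synthase, from 57.0 to 17.1 FPKM. This list had a camera adjusted p of 2.14e-07 and an adjusted p = 0.171 with an estimated correlation. Glycolysis genes fell in 15 of 24 cases, rose in 5 and did not pass in 4, also adjusted over the list alone. LDHA, lactate dehydrogenase A, fell from 255 to 97.7 FPKM, while TIGAR, a p53 target that lowers glycolytic flux, rose from 8.66 to 35.7 FPKM and the glucose transporter gene SLC2A3 from 7.47 to 15.2 FPKM. Its camera adjusted p was 0.0216, and adjusted p = 0.311 with an estimated correlation. Platinum transport and metallothionein genes were mixed. Of 17 tested 8 rose, 5 fell and 4 did not pass, and 6 fell adjusted over the list alone. MT2A, a metallothionein, rose from 125 to 401 FPKM, while the efflux pump genes ABCC4 and ABCC2 fell from 3.87 to 1.01 FPKM and from 6.04 to 2.97 FPKM. The list had a camera adjusted p of 0.591 (adjusted p = 0.766 with an estimated correlation), and its mean, 0.09, had another sign than its median, -0.06. The test, which compares the list with other genes, pointed down, and the list median minus that of all genes was -0.23.

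Ovarian genes changed one by one. Of 18 steroidogenic genes tested, 8 rose, 6 fell and 4 did not pass (the same adjusted over the list alone), against 7 that rose and 9 that fell with trimmed mean of M values scaling. NR5A1, the steroidogenic factor SF-1, rose from 14.1 ± 0.176 to 33.7 ± 2.69 FPKM (SD, n = 3), FDXR rose as given above, and AKR1C3, an aldo-keto reductase, fell from 20.1 to 8.59 FPKM. The camera adjusted p was 0.749 (adjusted p = 0.861 with an estimated correlation). The median, 0.11, and the mean, 0.18, of the steroidogenic list were above 0. The test, which compares the list with other genes, pointed down, and the list median minus that of all genes was -0.06. Of 30 granulosa cell markers listed, 19 were tested, and the others were absent or too low for testing. Among the 19 tested, 11 rose, 6 fell and 2 did not pass, also adjusted over the list alone. With trimmed mean of M values scaling, 9 rose and 7 fell. KITLG, the KIT ligand, rose from 19.0 ± 1.23 to 61.1 ± 12.1 FPKM (SD, n = 3), and FOXL2 and NR5A1 rose with it. The camera adjusted p was 0.647, and adjusted p = 0.766 with an estimated correlation.

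Markers of other cell types were looked at because the labels' cell type field calls this line fibroblast. COL1A1, COL1A2, VIM at 429 FPKM and MMP2 at 185 FPKM in control cells were abundant. Of 16 fibroblast and stromal markers listed, 12 were tested. Among the 12 tested, 11 fell and 1 did not pass, also adjusted over the list alone (camera adjusted p = 1.28e-06). The fibroblast list had an adjusted p = 0.232 with an estimated correlation, and 3 of its genes are also in the matrix list. Of 17 epithelial markers listed, 7 were tested, and the others were absent or too low for testing. Among the 7 tested, 6 fell and 1 rose, also adjusted over the list alone. KRT14 was at 194 ± 18.7 FPKM in control and 23.3 ± 3.44 in cisplatin libraries (SD, n = 3). KRT18 was at 164 and 49.9 FPKM and KRT7 at 79.5 and 35.7 FPKM. The epithelial list had a camera adjusted p of 0.01 and an adjusted p = 0.227 with an estimated correlation. CSF1R was the 1 immune marker tested and fell from 2.65 to 0.960 FPKM, also adjusted over the list alone (camera adjusted p = 0.151, and adjusted p = 0.285 with an estimated correlation). Among 3 endothelial markers tested, ESAM and EGFL7 rose to 3.06 and 8.85 FPKM and TEK fell from 5.70 to 0.426 FPKM, also adjusted over the list alone. That list had a camera adjusted p of 0.964 (adjusted p = 0.969 with an estimated correlation), and its median, 0.76, had another sign than its mean, -0.14. No theca or oocyte marker reached the level needed for testing, and the highest were GLI1 at 0.991 and 0.317 FPKM and ZP3 at 0.379 and 0.534 FPKM in control and cisplatin cells.

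Most mitochondrially encoded mRNAs fell, by different amounts. Of 13 tested, 8 fell, 1 rose and 4 did not pass, also adjusted over the list alone, and 11 fell and 0 rose with trimmed mean of M values scaling. MT-CYB fell from 2912 ± 83.7 to 1337 ± 88.8 FPKM (SD, n = 3), MT-ND4L from 1975 ± 146 to 939 ± 263, and MT-ATP8 from 33.4 ± 8.0 to 18.1 ± 5.58. MT-ND4L overlaps MT-ND4 and MT-ATP8 overlaps MT-ATP6, so these values are uncertain, and the call of MT-ATP8, with a log2 fold change of -0.87, was lost in 5 alternatives. These were without cisplatin replicate 1 (-0.61, adjusted p = 0.0606), without control replicate 1 (-0.73, 0.0655), without control replicate 3 (-0.82, 0.0595), without a filter (-0.87, 0.0618) and with the replicate block (-0.87, 0.116). The list had a camera adjusted p of 0.00506 and an adjusted p = 0.20 with an estimated correlation. With quantile normalization it did not pass (adjusted p = 0.0965), and its median lay 0.31 below that of all genes in place of 0.68. Among 29 nuclear genes of oxidative phosphorylation, 17 rose, 2 fell and 10 did not pass, with 16 that rose adjusted over the list alone, against 8 that rose and 6 that fell with trimmed mean of M values scaling and 18 that rose and 5 that fell without cisplatin replicate 1. COX6C rose from 24.0 to 38.0 FPKM, COX5B from 50.2 to 75.6 and NDUFA4 from 48.2 to 71.7 (camera adjusted p = 0.17, and adjusted p = 0.799 with an estimated correlation). Of 38 cytosolic ribosomal protein genes, 15 rose, 3 fell and 20 did not pass, with 10 that rose adjusted over the list alone, against 4 that rose and 4 that fell with trimmed mean of M values scaling and 17 that rose and 6 that fell without cisplatin replicate 1. RPS19 was at 76.8 ± 1.07 and 161 ± 32.8 FPKM (SD, n = 3), RPL38 at 25.4 and 39.7 and RPL19 at 201 and 307 in control and cisplatin cells. These genes have many processed pseudogenes that can share reads, and the list had a camera adjusted p of 0.325 (adjusted p = 0.861 with an estimated correlation). Among 7 nuclear retained and RNA quality transcripts tested, 6 rose and 1, MALAT1, did not pass, also adjusted over the list alone. Hosts of small nucleolar RNAs led this list, with SNHG8 at 17.6 and 54.4 FPKM, GAS5 at 33.2 and 99.2 and SNHG1 at 9.98 and 22.9 (camera adjusted p = 0.0288, and adjusted p = 0.225 with an estimated correlation), and the list did not pass with a filter of 5 FPKM (adjusted p = 0.0748). The list medians had the same sign with the deposited values and under 5 other scalings, except those of the nucleotide excision repair, steroidogenic and ribosomal protein lists.

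**Figure D2:**
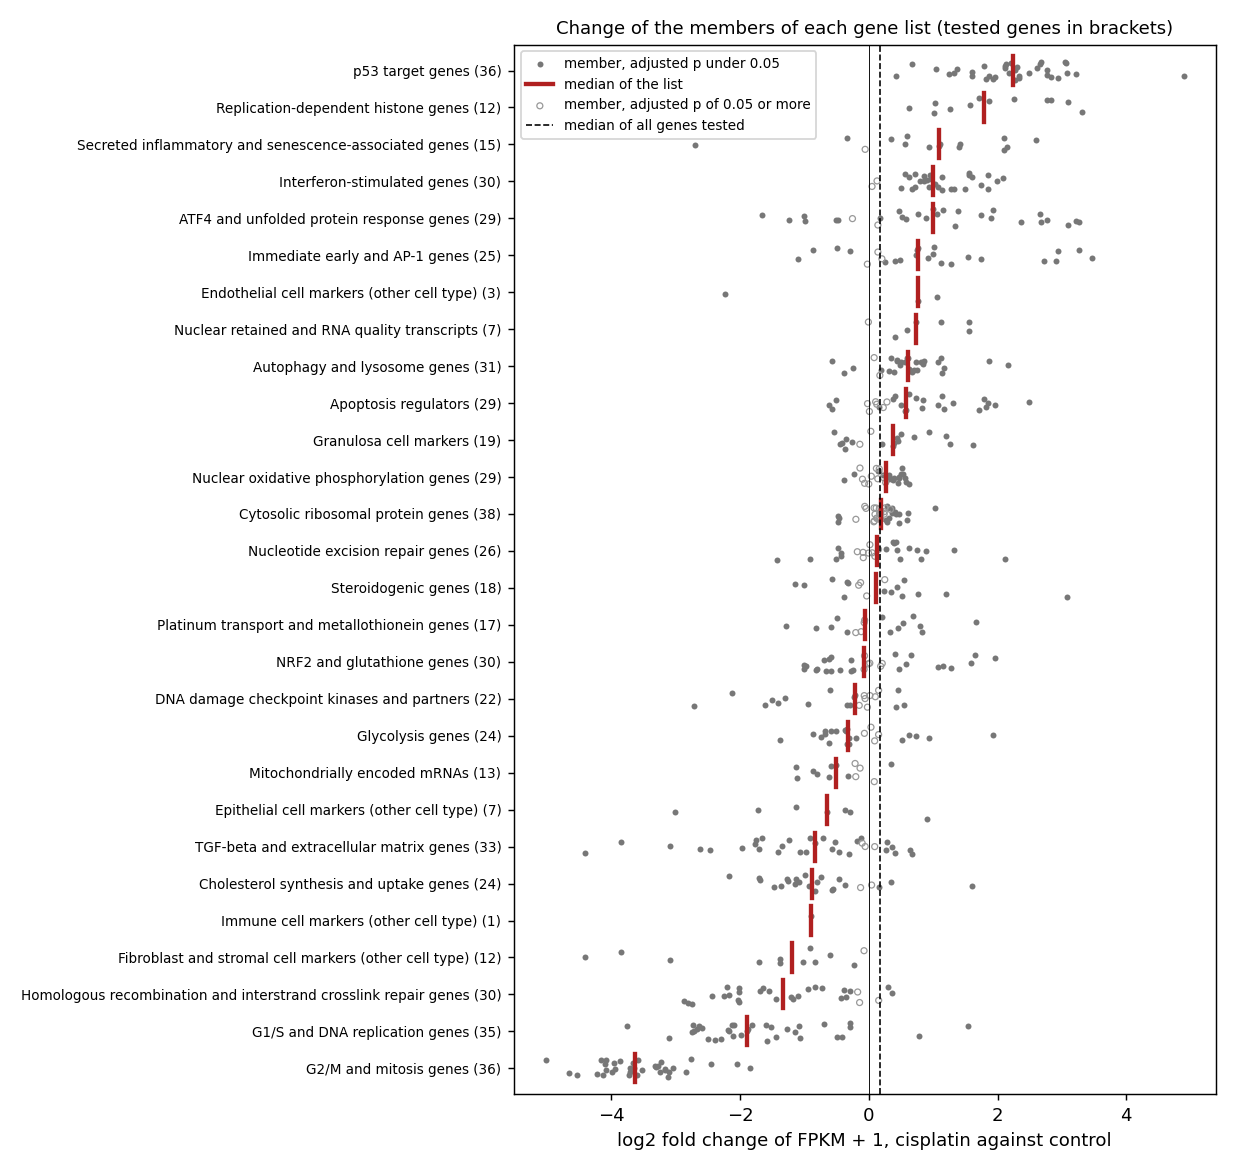
Log2 fold change of FPKM + 1 (horizontal axis) of each tested member of the 28 gene lists with a tested gene, ordered by median, where filled points passed and open points did not, red bars are list medians and the dashed line is the median of all genes (0.17). The list medians run from -3.63 for G2/M and mitosis genes to 2.24 for p53 target genes.

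**Figure D3:**
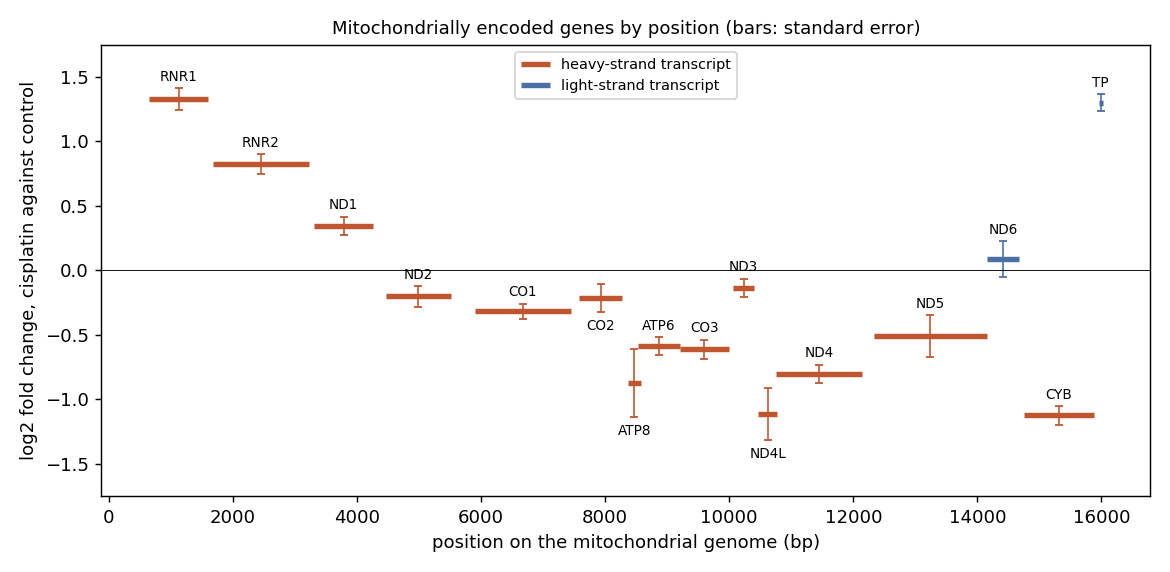
Log2 fold change of FPKM + 1 (vertical axis, bars are SE) of the 16 mitochondrial genes tested, drawn from start to end in bp. Red marks genes annotated as heavy-strand transcripts and blue those annotated as light-strand transcripts. Along the heavy strand the values go from 1.33 for MT-RNR1 to -1.12 for MT-CYB.

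Genes with a long genomic span fell relative to genes with a short span. Because cisplatin adducts are known to stall RNA polymerase, this comparison was set before the data were examined. The median log2 fold change was -0.20 for 2175 genes over 100 kb and 0.32 for 3648 genes under 10 kb. Among 117 genes over 500 kb, 89 fell and 12 rose, with a median of -1.10, and with trimmed mean of M values scaling the median was -1.24. EXOC4, an exocyst gene of 814 kb, fell from 13.2 ± 0.280 to 0.640 ± 0.0827 FPKM (SD, n = 3). TENM3 fell from 32.4 ± 1.54 to 3.36 ± 0.347 FPKM, and TENM2 from 13.8 ± 0.524 to 1.42 ± 0.152 FPKM. These examples were chosen after their values were seen, as the largest falls of that class on the scale of log2(FPKM + 1). By the ratio of mean FPKM other genes of the class fell further, such as CADPS2 (35.8-fold, against 20.6-fold for EXOC4). Medians of intermediate classes were 0.36 for 5 to 10 kb, 0.21 for 20 to 50 kb, 0.07 for 50 to 100 kb (-0.10 with trimmed mean of M values scaling), -0.09 for 100 to 200 kb and -0.40 for 200 to 500 kb. Across genes, which are not independent replicates, Spearman's rho of span and log2 fold change was -0.27. The set of long genes had a camera adjusted p of 3.95e-12 and an adjusted p = 0.292 with an estimated correlation. The set of short genes had a camera adjusted p of 0.00632, also with an adjusted p = 0.292 with an estimated correlation. Without a filter on low values, with 4024 long and 16374 short genes, the short genes did not pass (adjusted p = 0.296), the median of long genes lay 0.0715 below that of short genes in place of 0.52, and rho was -0.0878. Long genes still passed there (adjusted p = 4.19e-10). The mean log2 value of long genes minus that of short genes was also taken per library. It was 0.161 ± 0.0121 in control and -0.417 ± 0.105 in cisplatin libraries (SD, n = 3). Each of the 3 cisplatin libraries was lower than any control. The two-sided exact permutation p was 0.1, the smallest that 3 against 3 can give. Cisplatin replicate 1 was lowest, at -0.539, against -0.361 and -0.352 in replicates 2 and 3. Without replicate 1 the median of long minus short genes was -0.459 in place of -0.52, and rho was -0.234. Both sets still passed then (camera adjusted p = 2.91e-09 for long and 0.0403 for short genes).

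**Figure D4:**
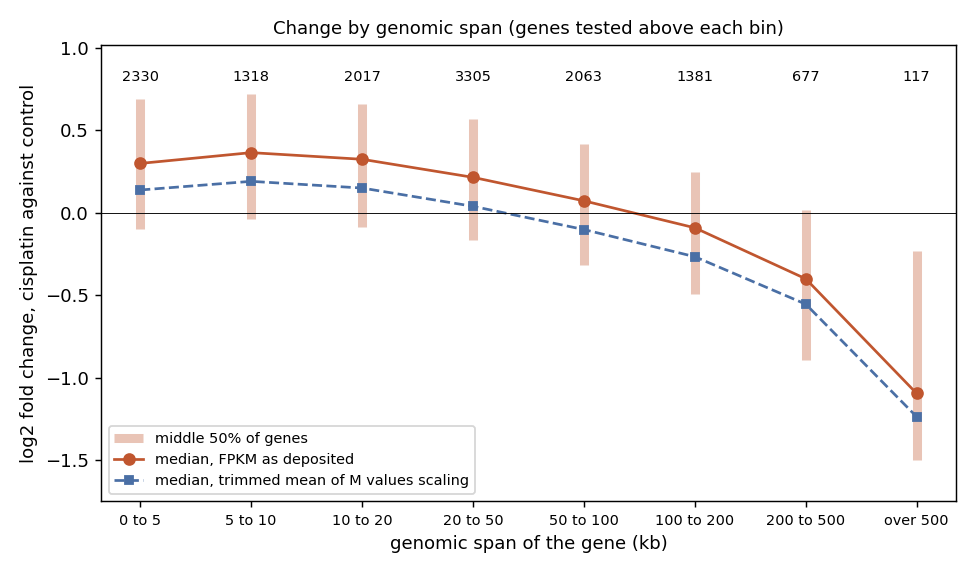
Median log2 fold change of FPKM + 1 (vertical axis) of genes in 8 classes of genomic span in kb, with the deposited values (red line, bars are the middle 50% of genes) and with trimmed mean of M values scaling (blue dashed line). The median goes from 0.30 in genes under 5 kb to -1.10 in genes over 500 kb.

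Libraries of a group were close to each other and far from the other group. Pearson's r of log2(FPKM + 1) was 0.994 for each pair of control libraries, 0.985 to 0.995 within cisplatin and 0.869 to 0.878 between groups. Chi-square per degree of freedom of recovered reads was 2.10 to 3.77 between control libraries and between cisplatin replicates 2 and 3, above the value near 1 of repeated sequencing of a library, and up to 23.3 with cisplatin replicate 1. Cisplatin replicate 1 was the least similar of its group, at 0.986 and 0.985 with replicates 2 and 3 against 0.995 between those. The 10 highest genes held 19.2 ± 0.0794% of the FPKM sum in control and 15.6 ± 0.256% in cisplatin libraries (SD, n = 3). Mitochondrial mRNAs held 17.5 ± 0.321% and 12.7 ± 0.272%, mitochondrial rRNAs 2.11 ± 0.147% and 3.75 ± 0.13%, and ribosomal protein genes 3.25 ± 0.0306% and 3.59 ± 0.384%. Each of these shares had a two-sided exact permutation p of 0.1, the smallest possible, since no control library overlapped the cisplatin libraries. The share of ribosomal protein genes was 4.03% in cisplatin replicate 1 and 3.32% and 3.42% in the others.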

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

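Alternatives using voom on recovered reads and protein-coding genes alone were chosen after the data were seen. Of the values for single named genes, 1761 were unchanged in call and direction and 10 lost the call, among them 5 of MT-ATP8. For gene lists 565 were unchanged, 24 lost the call, 7 gained it and 18 turned, and for gene span 64 kept their direction and any call, though not always their size, 3 lost the call and 1 value of rho moved by over 1.5 times. Of the counts and shares 75 stayed within 1.5 times and 6 did not. List values below are list medians minus the median of all genes, and the sign of a test, set by all members, can differ from the sign of the median. Except where said, the cause was not tested.

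With a replicate block 5962 genes rose and 3400 fell. Deviations from the group mean had correlations of 0.00435, 0.0321 and -0.0742 between control and cisplatin libraries of the same number, and not every library correlated best with its own number, so the numbers give no hint of pairs. The block ended the call of MT-ATP8 and turned the test of endothelial markers (0.59), and it changed no other call of a named gene or list. When each library was left out in turn, 5548 to 6609 genes rose and 3134 to 3812 fell. Over these 6 fits the secreted inflammatory genes had values of 0.83 to 0.95, lost without cisplatin replicate 1 (0.93), and the endothelial markers 0.44 to 0.68, turned without cisplatin replicate 2 (0.68).

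With a filter of 5 FPKM 3872 genes rose and 2132 fell, 600 of them at least 2-fold, as fewer genes (7776) were tested. It ended the calls of secreted inflammatory genes (0.98) and nuclear retained transcripts (0.74) and turned the test of steroidogenic genes (0.0574). Without a filter the steroidogenic genes turned (0.0692), and nuclear oxidative phosphorylation (0.21) and ribosomal protein genes (0.17) passed. The call of short genes ended there (median 0.0272 in place of 0.32), and rho of span and change was -0.0878 in place of -0.27, with long minus short genes at -0.0715 in place of -0.52. A pseudocount of 0.1, which compresses low values less, gave 1786 rises of at least 2-fold. Falls of at least 2-fold were 1483 with TPM scaling without the highest and mitochondrial genes and 1720 with voom.

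The test of nucleotide excision repair genes turned with trimmed mean of M values (-0.0513), median of ratios (-0.0512), quantile normalization (-0.0641), library weights (-0.12) and voom (-0.0586). That of endothelial markers turned with TPM (0.65), trimmed mean of M values (0.58), median of ratios (0.58), quantile normalization (0.57), TPM without the highest and mitochondrial genes (0.65), voom (0.68) and protein-coding genes only (0.61). Quantile normalization ended the call of mitochondrial mRNAs (-0.31), and library weights that of secreted inflammatory genes (0.84).

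With fry, which asks whether a set changed at all and not whether it changed more than other genes, nucleotide excision repair (-0.0454), granulosa (0.20), nuclear oxidative phosphorylation (0.0936), immune (-1.07) and endothelial (0.59) genes passed. The steroidogenic genes (-0.0635) passed with the direction turned (adjusted p = 0.0263), and platinum transport genes (-0.23) turned without passing (adjusted p = 0.571).

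With an estimated correlation, where camera also uses only the 4 residual degrees of freedom of the fit, no list and neither span set (long minus short -0.52, short 0.32) passed. The secreted inflammatory and immediate early lists had estimated correlations of -0.0121 and -0.0257, below the preset 0.01, so correlation is not why these were lost. The values were 2.07 for p53 targets, -3.80 for G2/M, -2.06 for G1/S, 1.62 for histones, -1.50 for homologous recombination, -0.39 for checkpoint genes, 0.41 for apoptosis, -1.05 for cholesterol, 0.92 for secreted inflammatory, 0.83 for interferon-stimulated and 0.83 for ATF4 genes. They were 0.60 for immediate early genes, -1.001 for matrix, 0.44 for autophagy, -0.68 for mitochondrial mRNAs, -0.49 for glycolysis, 0.57 for nuclear retained transcripts, -1.37 for fibroblast and -0.81 for epithelial markers.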

Other observations

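The families named by symbol stem, the gene classes, the test of mitochondrial mRNAs without rRNA and the test over both mitochondrial strands were chosen only after the results were seen. Protein-coding genes grouped by the letters of their symbol before the first digit, 129 stems with at least 10 tested members, gave groups beyond the fixed lists, though the stems HIST, COL, KIF and DUSP share genes with those. No stem passed with an estimated correlation (lowest adjusted p = 0.832). Zinc finger genes with the stem ZNF rose in 234 of 325 cases and fell in 32 (median 0.30 above all genes, camera adjusted p = 0.000115, and adjusted p = 0.881 with an estimated correlation), and 200 rose and 43 fell with trimmed mean of M values scaling. Dual specificity phosphatases (DUSP) rose in 12 of 16 cases, with 0 that fell. Nucleoporins (NUP) fell in 16 of 19 cases, with 0 that rose, GALNT genes, which start O-linked glycosylation, in 10 of 11 (0 rose) and myosins (MYO) in 9 of 11 (2 rose). Kinesins (KIF) fell in 17 of 26 cases (3 rose), collagens (COL) in 16 of 24 (4 rose) and annexins (ANXA) in 8 of 11 (2 rose). Histones (HIST) rose in 22 of 22, again only for the transcripts that the mRNA kit captured. In all, 3 stems were higher and 6 lower than other genes at the preset correlation, and with trimmed mean of M values scaling ANXA did not pass (adjusted p = 0.0568, median -0.86 against -0.65 with the deposited values) while ZSCAN (0.0401) and KIAA (0.0441) did. The median span was 24.2 kb for ZNF genes and 170 kb for MYO genes.

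LincRNA and antisense genes rose more often than they fell under both scalings looked at. Of 528 lincRNA genes tested, 283 rose and 117 fell, with a median log2 fold change of 0.36, and of 464 antisense genes 240 rose and 63 fell, with a median of 0.37, against 0.15 for 10944 protein-coding genes, of which 5069 rose and 3138 fell. With trimmed mean of M values scaling 246 lincRNA genes rose and 140 fell, 215 antisense genes rose and 82 fell, and 3758 protein-coding genes rose and 4207 fell. No test compared the classes. Without strand in the counting, reads of an antisense gene cannot be told from those of its partner.

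The fall of genes with a long span relative to short genes was set against properties that go with span. Partial Spearman rho of span and log2 fold change across genes was -0.20 given merged exon length, -0.27 given mean expression and -0.27 given GC content of the longest transcript, each beyond the bound of -0.1 set beforehand, so none of these alone accounts for the trend. Genes over 100 kb had the lower median in 9 of 9 strata of exon length and expression, from -0.76 to -0.19 relative to genes under 10 kb. Loss of transcript along long genes after cisplatin would give this, but so would differences in transcript stability or cell cycle stage that go with span, which were not tested, so it stays a hypothesis.

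Mitochondrial heavy-strand genes tended to a lower log2 fold change the farther they lie from the promoter (rho -0.78 over 14 genes). The values went from 1.33 for MT-RNR1 and 0.83 for MT-RNR2 to -1.12 for MT-CYB. MT-CO2 (-0.21), MT-ATP6 (-0.59), MT-CO3 (-0.61), MT-ND3 (-0.13), MT-ND4 (-0.80) and MT-ND5 (-0.51) each lay above a gene nearer to the promoter. Over the 12 heavy-strand mRNAs without the rRNAs rho of position and change was -0.66 (permutation p = 0.0242), which argues against capture of rRNA as the whole cause. The permutations over mitochondrial genes took genes as independent units, which they are not. MT-ND4L overlaps MT-ND4 and MT-ATP8 overlaps MT-ATP6, so these p-values are only descriptive. Given gene length the partial rho over 14 heavy-strand genes was -0.80, and without cisplatin replicate 1 rho was -0.75, so neither gene length nor that library alone accounts for it. With MT-ND6 of the light strand placed by distance from its own promoter, rho over 15 genes was -0.82 (permutation p = 0.00029), but the 14 heavy-strand genes alone had -0.78, so a loss of transcript with distance from the promoter of either strand stays an open hypothesis. MT-TP, a tRNA gene near the light-strand promoter, rose from 694 ± 37.4 to 1710 ± 6.36 FPKM (SD, n = 3). The strand of MT-ND6 and MT-TP is that of the annotation. Without strand in the counting, their reads cannot be told from heavy-strand reads at the same positions. Neither gene can then speak for the light strand.

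Cisplatin replicate 1 differed from the mean of the other cisplatin libraries with an SD of 0.27 on the log2 scale over genes, against 0.14 to 0.15 for the control libraries. Its deviation had a Spearman rho of -0.35 with merged exon length, against -0.04 to 0.01 in control libraries, and of 0.47 with GC content, against -0.24 to 0.15, so a length bias and a GC bias of that library are both candidate explanations and both stay open; given the other, the partial values were -0.32 and 0.45. A bound of 0.2 for GC content was also passed by control replicate 2 (-0.24), which does not stand apart. Cisplatin replicates 2 and 3 passed both bounds with the other sign, at 0.32 and 0.27 for exon length and -0.26 and -0.51 for GC content, but the mean each is compared with includes replicate 1. The slope of its deviation on the change in the other cisplatin libraries was -0.013 (SE 0.00299), and -0.00366 and -0.000118 when no library was used on both sides, below the 0.05 that a stronger response to cisplatin in that culture would need. RN7SL2, a short signal recognition particle RNA, was at 209 FPKM in this library and at 17.7 and 16.9 in the other cisplatin libraries, and at 151 in control replicate 1 against 37.8 and 47.5 in the other controls.

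The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division called 9566 genes, and 1 of the 10 gave as many, which is the real division itself. The highest of the others gave 0. Each of those puts control and cisplatin libraries on both sides, so the difference between the groups becomes spread and few calls were bound to result. The contrast therefore cannot decide whether chance played a part.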
